A study of Mus musculus with 20 samples.

How the data were processed

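The data were 20 Affymetrix Mouse430_2 arrays of whole liver RNA, 1 array per mouse, with 1 value per probe set and array. The groups were non-manipulated control (n = 5), minor trauma (n = 3), 1.5 h of hemorrhagic shock with severe trauma (n = 4), and the same followed by 1 h (n = 4) or 4.5 h (n = 4) of resuscitation, as the labels give them. Per the labels, the mice were male C57BL/6 aged 8 to 12 weeks, RNA came from TRIzol extraction of whole liver, 1 µg of it was copied into cDNA from oligo-dT primers, and biotin-labelled cRNA was made by in vitro transcription. The deposited values are intensity signals that the authors computed with MAS5 per the submitters' processing notes, on a linear scale, and its version was not given in the sources used here. The series is the Affymetrix part of a study on 2 platforms, and the other platform was not analysed here. What the minor trauma was and when those mice were sampled was not given in the sources used here.

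The deposited signals were not scaled between arrays. Their 2% trimmed means ran from 64.93 to 166.6, a ratio of 2.565, and their medians from 14.05 to 29.11. The plan written before the data were examined took the values as scaled and kept them as deposited. Because the table was unscaled, quantile normalization, which the plan held as an alternative, was made the main setting before any test was run, and the fit of the values as deposited is reported beside it. A pseudocount of 6, the 25th percentile of all values, was added before taking log2, and log2 values were quantile normalized over the 20 arrays. A probe set was kept if it lay above the median of its own array on at least 3 arrays, which left 27274 probe sets. Gene names came from the platform annotation with symbols updated through the reference tables. Of the probe sets, 34945 had 1 gene, 932 had several and 9160 none, and 64 were control probe sets. Only those with 1 gene were used, and for each gene the kept probe set with the highest mean stood for it, which left 12832 of 18193 genes and removed 5361. Named genes whose other probe sets were called in the opposite direction were Hspa4 and Rora from 1 h to 4.5 h, each with 1 such probe set.

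Genes were tested with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 1 linear model of 5 group means over the 20 arrays, 7 contrasts and moderated statistics with an intensity trend. The p values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p of at most 0.05. A second count took the called genes with a change of at least 2-fold. The F test over the 5 groups was adjusted in the same way. The comparisons were minor trauma, shock, and 1 h and 4.5 h of resuscitation against control, shock against minor trauma, 1 h of resuscitation against shock, and 4.5 h against 1 h. Figures were drawn with python 3.11.15, matplotlib 3.10.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

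The 34 gene lists of liver functions, signalling responses and cell type markers were written from general knowledge before the data were examined and were tested with camera at a preset correlation of 0.01 between genes. P values were adjusted over the 34 lists. Of 15 gluconeogenesis and cAMP-responsive genes 13 were matched. G6pc, listed under the symbol G6pc1, was not matched, so no count of that list holds it. Some lists share members, so their calls are not independent of each other. Il6 and Bcl3 are in the IL-6 and NF-kB lists, and Mt1, Mt2 and Lcn2 in the acute phase and glucocorticoid lists. The immediate early list shares Atf3 with endoplasmic reticulum stress, Junb with IL-6 signalling and Btg2 with p53 targets. It also shares Nr4a1 with gluconeogenesis, Ier3 with NF-kB targets and Dusp1 with the glucocorticoid list. The glucocorticoid list shares Igfbp1 and Irs2 with gluconeogenesis, Ddit4 with hypoxia, Cdkn1a with p53 targets and Cebpd with IL-6 signalling. Irf1 is in the NF-kB and interferon lists, and Hmox1 in the hypoxia and NRF2 lists. Each test was repeated with the correlation estimated from the data and with fry. Members of a list were counted as called over all genes tested and, separately, after adjustment over the list alone. Named genes were the 10 largest positive and the 10 largest negative changes that passed the test in each comparison with control, the 6 largest in the 3 other comparisons, and up to 4 members of each list with the largest change that passed the test, or the 2 with the smallest p. Genes known only by clone or locus names were left out of this naming. Genes named in the text were followed over the groups. For 65 of the 670 named gene results the gene lay at or below the median of its own array on every array of the lower group, a limit chosen after the data were seen. The fold is then a bound: the mean of the higher group over the mean of, per array of the lower group, the higher of the array median and the gene's own value, all after normalization.

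Alternatives fixed before the data were examined were median centring, no pseudocount or one of 18 (the median of all values), no filter or a filter at the 70th percentile, all probe sets, the mean of a gene's probe sets, no trend, a robust fit, array weights, only the arrays of the 2 groups, a replicate block and leaving out each array in turn. The values as deposited were the planned main setting. Chosen after the data were seen were trimmed mean scaling, the sets of arrays with and without poly-A spike signal as a block and each set alone, and leaving out control array 5 with minor trauma array 3. The choice of the weighed patterns and of the gene families in the closing section was also made after the data were seen. RNA integrity was taken from the 3′ and 5′ probe sets of Gapdh and beta-actin and compared by a two-sided exact permutation test over 8 tests. Expected overlaps assumed independent lists. Correlations between comparisons that share controls were set against 100 simulations of unchanged groups, with the controls shared or split as in the value beside them. Up to 100 other splits of the arrays were tested per comparison, and 10000 random lists matched on expression were drawn for the clock genes. Arrays were never regrouped by their values.

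The pipeline was tested on simulated data with 200 changed genes among 12832 in each comparison. At a log2 change of 0.5, 1 and 2 it recovered 18.3%, 62.8% and 95.2% for minor trauma against control, 15.9%, 76.3% and 100% for shock, 32.7%, 67.6% and 95.9% for 1 h and 23%, 65.6% and 98.7% for 4.5 h. For shock against minor trauma it recovered 18.6%, 60.6% and 96%, for 1 h against shock 9.46%, 63.2% and 95.7%, and for 4.5 h against 1 h 27.6%, 72.8% and 96.7%. Of the calls, 8.46%, 3.73%, 4.86%, 5.76%, 3.91%, 3.54% and 2.9% were false in this order. The simulated values were drawn independently for each gene and array from normal distributions, without an outlying array. These rates therefore do not cover arrays that stand apart from their group, such as control array 5 and minor trauma array 3.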

Results

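Gene expression was measured in whole liver of male C57BL/6 mice aged 8 to 12 weeks on 20 Affymetrix Mouse430_2 arrays. The arrays fell into 5 groups that model a time course and a range of injury severity. There were 5 arrays from non-manipulated control mice, 3 from mice with minor trauma, and 4 from mice taken at the end of 1.5 h of hemorrhagic shock with severe trauma (the shock group). A further 4 arrays came from mice given 1 h of resuscitation after that shock and trauma, and 4 from mice given 4.5 h of resuscitation. The labels did not say what the minor trauma consisted of or when those animals were sampled. Of the probe sets 34945 stood for a single gene, and 12832 genes were bright enough to be tested. The number of arrays, 3 to 5 per group, limits the precision of every value below.

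The resuscitated liver at 4.5 h differed most from all other groups. Of the genes tested, 5823 (45.4%) differed among the 5 groups by limma's F test, and without the array labelled control 5 the count was 6026. The first principal component held 35.1% of the variance and placed the 4.5 h arrays at 55.6 to 65.6 and every other array at 2 or below. Minor trauma array 3 lay apart on the third component, at -58, and had the lowest array weight, 0.18. The array labelled control 5 correlated best with minor trauma array 2 (r = 0.983 across genes), and minor trauma arrays 1 and 2 both correlated best with it. Cyp2b10 read 11.83 on that array on the log2 scale, 3.82 to 6.14 on the other 4 control arrays and 11.45 to 12.36 on the minor trauma arrays. The 3′ to 5′ signal ratio of Gapdh, a measure of RNA integrity, averaged -0.30 ± 0.20 (SD, log2, n = 5) in controls and -0.41 to -0.30 in the other groups, and that of beta-actin 0.79 ± 0.26 and 0.72 to 0.90. The groups were compared by an exact permutation test (two-sided exact permutation p = 0.444 to 0.944 over 8 tests, Benjamini-Hochberg adjusted 0.944 for all). The arrays also fell into 2 sets by the poly-A spike-in control dap: 10 arrays, 2 per group, read 374 to 1830 and the other 10 (3 control, 1 minor trauma and 2 of each remaining group) 0.252 to 3.26. Results with this set as a block and within each set stand beside the counts below. The deposited signals were not scaled between arrays, and without normalization the median log2 fold change of all genes tested was 0.20 for minor trauma, -0.03 for shock, -0.12 for the 1 h group and -0.27 for the 4.5 h group against control. It was -0.22 for shock against minor trauma, -0.09 for the 1 h group against shock and -0.16 for the 4.5 h group against the 1 h group. After quantile normalization these medians lay between -0.09 and -0.002, and all changes are given after it. Where a gene lay at or below the median of its own array on every array of the lower group, that group gave only a bound, and the fold is written as at least N-fold. It sets the higher group's mean against the array median, 4.6 after normalization. Among the 5 control arrays, Cxcl2, Atf3, Hspa1a and Gzmb lay above the median on 1, Gadd45b, S100a9, Fosl2 and Mx2 on 2, S100a8 and Adm on 3, and Cyp2b10, Orm3, Pfkfb3 and Ccl5 on 4. Values after ± are standard errors of the log2 fold change unless marked SD, and adjusted p values of single genes are limma's.

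**Figure D1:**
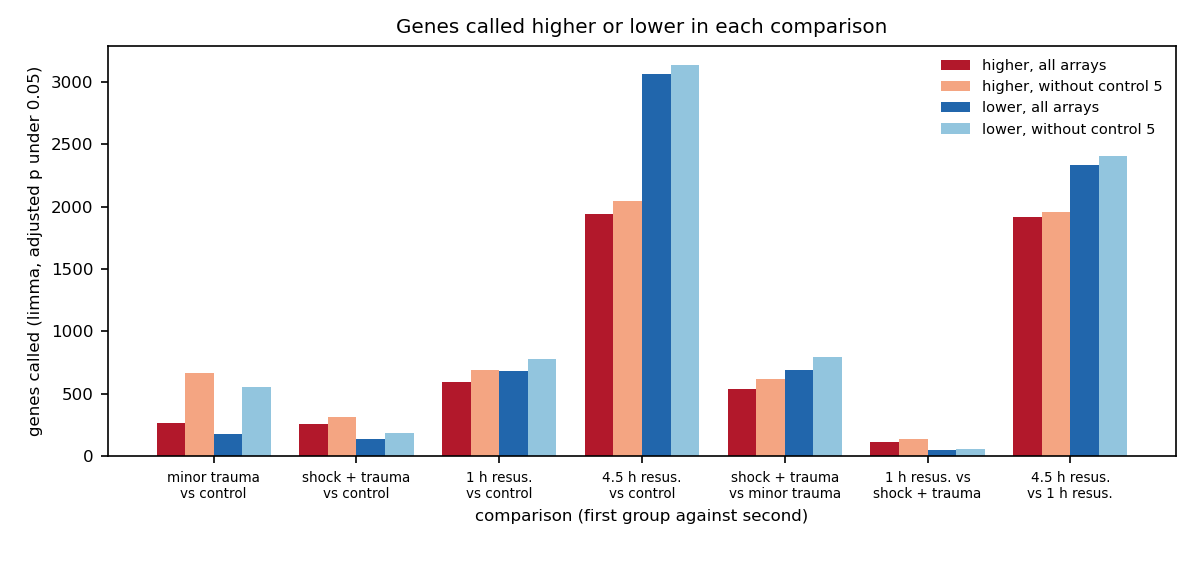
Number of genes with limma adjusted p under 0.05 in each of the 7 comparisons, higher (red bars) and lower (blue bars). Dark bars are for all 20 arrays and light bars for the arrays without the one labelled control 5. The 4.5 h group against control had 1937 higher and 3059 lower genes, against 260 and 139 for shock against control.

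Of the 34 gene lists fixed before the data were examined, camera called 11 in minor trauma, 12 in shock, 15 at 1 h and 17 at 4.5 h against control, 10 in shock against minor trauma, 8 from shock to 1 h and 10 from 1 h to 4.5 h. With an estimated correlation 0, 6, 6, 9, 1, 2 and 2 of these calls held. In shock and at 1 h they were the immediate early genes, neutrophil markers, NF-kB targets, IL-6 signalling, p53 targets and glucocorticoid-inducible genes. At 4.5 h they were the interferon-induced genes, immediate early genes, neutrophil markers, NF-kB targets, IL-6 signalling, p53 targets, monocyte markers, cytochromes P450 and bile acid genes. In shock against minor trauma the immediate early genes held (camera adjusted p = 0.00213 with an estimated correlation). From shock to 1 h the neutrophil markers and NF-kB targets held (adjusted p = 0.0197 for both). From 1 h to 4.5 h the interferon-induced genes and cytochromes P450 did (adjusted p = 0.00537 and 0.0138). For the 6 lists in shock this adjusted p ran from 9.31e-06 for immediate early genes to 0.03 for NF-kB targets and IL-6 signalling. In 39 of the 238 list results the median, the mean and the test differed in sign, and 2 of these were called by camera (endoplasmic reticulum stress in shock and interferon-induced genes at 1 h). Some lists share members, Atf3 and Il6 among them, so the list calls are not independent of each other.

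**Figure D2:**
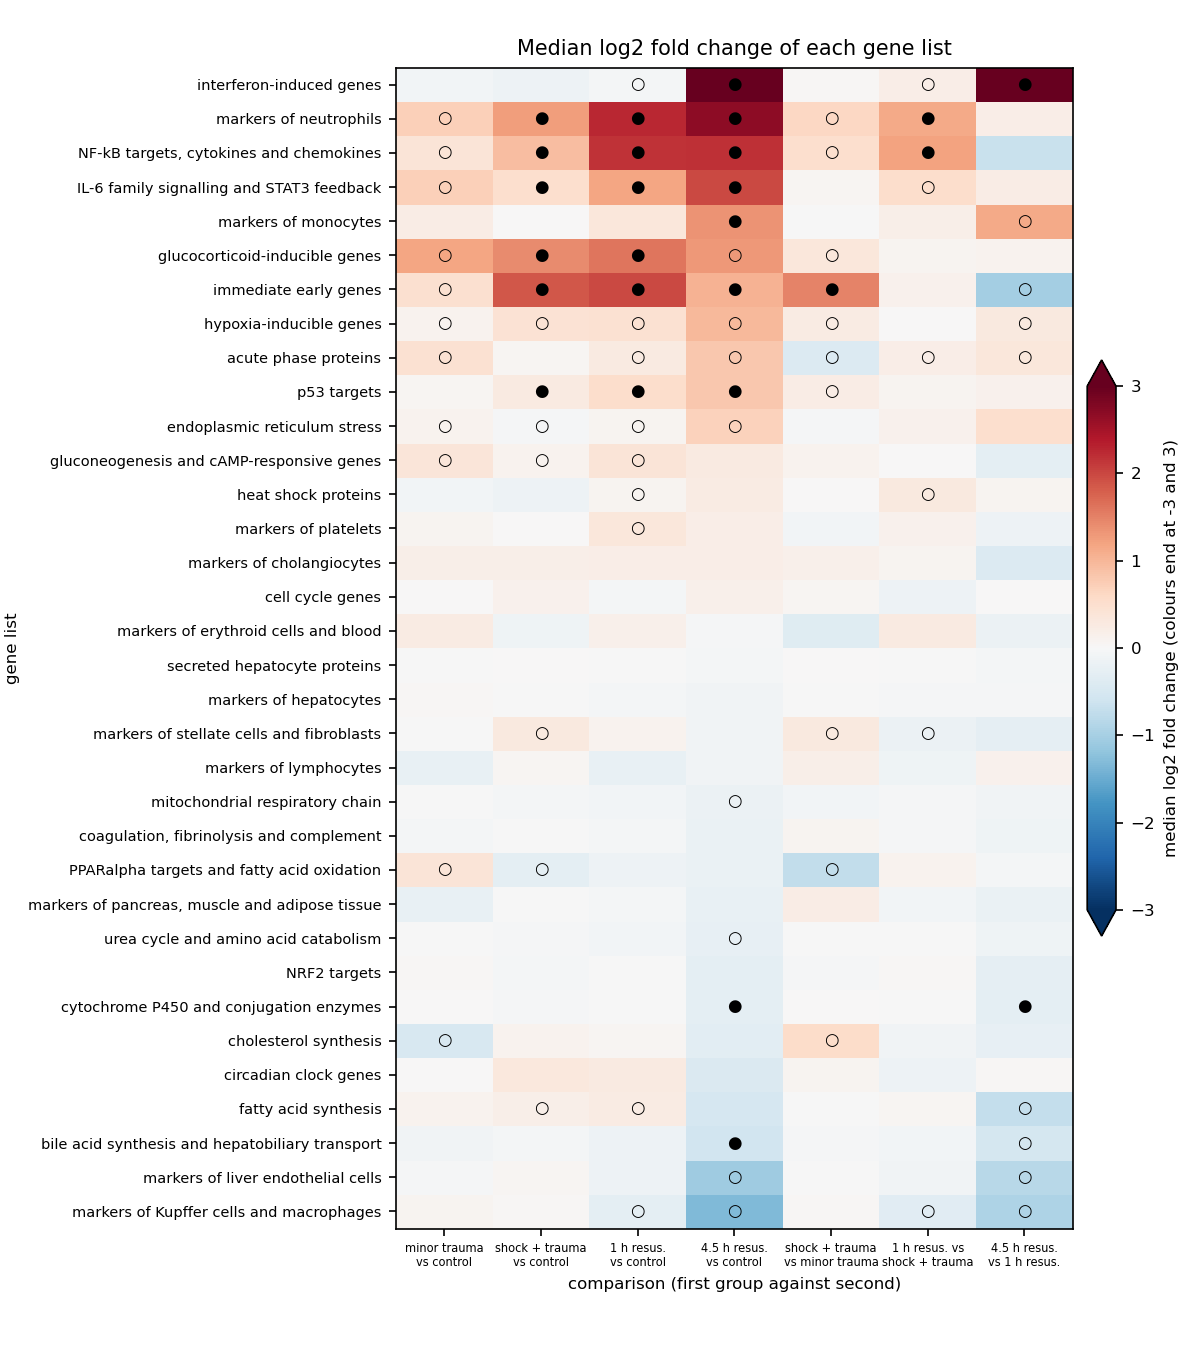
Median log2 fold change of each of the 34 gene lists (vertical) in the 7 comparisons (horizontal), with colours ending at -3 and 3; an open circle marks a camera call and a filled circle a call that held with an estimated correlation. Interferon-induced genes had the highest median, 3.62, in the 4.5 h group against control.

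Minor trauma was compared with the non-manipulated state. In this and the other comparisons with control, injury cannot be told apart from the manipulation that came with it, since the controls were non-manipulated. Nor can it be told apart from time of day, which the labels did not give. The largest change was in Cyp2b10, a drug-metabolizing cytochrome P450 induced through the nuclear receptor CAR, which rose 46.5-fold (log2 5.54 ± 1.04, adjusted p = 0.0151, n = 3 against 5). The acute phase gene Lcn2, which encodes an iron-trapping protein, rose 22-fold (4.46 ± 0.86, adjusted p = 0.0151), and the metallothioneins Mt2 and Mt1 rose 8.92-fold and 7.01-fold (adjusted p = 0.0229 and 0.0234). The stress gene Gadd45b rose 9.38-fold, the chemokines Cxcl1 and Cxcl13 8.73-fold and 6.93-fold, the growth factor Nrg4 5.6-fold, the neutrophil protein gene S100a8 5.04-fold and the acute phase gene Orm3 4.7-fold (adjusted p = 0.0151 to 0.0396). Arrdc3 fell most, 4.86-fold (-2.28 ± 0.49, adjusted p = 0.0209). It was followed by the tight junction gene Cldn1 (4.43-fold), Ddc (3.64-fold), Spaca4 (at least 1.18-fold), Enho (2.92-fold), Zfp467 (2.81-fold), the insulin receptor substrate Irs1 (2.75-fold), Dclk3 (2.67-fold), the Wnt target Lgr5 (2.64-fold) and Gbp6 (2.63-fold). For Cxcl13, Orm3, Cldn1, Spaca4, Irs1 and Lgr5 the arrays of both groups did not overlap, and for the other 14 of these 20 genes they did. Dclk3 and Lgr5 lay above their array's median on 1 of 3 minor trauma arrays. Alas1, the first enzyme of heme synthesis, rose by 2.06 ± 0.56 (adjusted p = 0.0462).

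Among the fixed lists, the acute phase proteins shifted up, with 11 of 28 measured genes higher and 0 lower (18 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 3.39e-12, adjusted p = 0.267 with an estimated correlation). Glucocorticoid-inducible genes had 9 of 20 higher (15 higher and 1 lower adjusted over the list alone; median 1.18, adjusted p = 8.18e-09), IL-6 family signalling 7 of 18 (9 over the list alone; 0.72, adjusted p = 1.76e-07), including Cebpd (1.88 ± 0.38) and Il1r1 (1.86 ± 0.46). Immediate early genes had 4 of 30 higher (9 over the list alone; 0.49, adjusted p = 7.83e-05), including Jun (2.02 ± 0.44) and Fosl2 (1.63 ± 0.35). Each of these 3 had an adjusted p = 0.267 with an estimated correlation. Neutrophil markers moved with them, with 2 of 12 higher (7 over the list alone; 0.73, adjusted p = 0.00021), S100a8 and S100a9 (adjusted p = 0.267 with an estimated correlation). NF-kB targets had 3 of 32 higher (5 over the list alone; 0.38, adjusted p = 0.000371), and PPARalpha targets 2 of 24 (7 over the list alone; 0.39, adjusted p = 0.000279), Cidec and Cpt2. Hypoxia-inducible genes had 2 of 28 higher (8 over the list alone; 0.11, adjusted p = 0.0277), and cholesterol synthesis genes 0 of 17 with 0 lower (3 lower over the list alone; -0.48, adjusted p = 0.00325). These 4 had an adjusted p = 0.556 with an estimated correlation. Endoplasmic reticulum stress genes had 3 of 23 higher (7 over the list alone; 0.11, adjusted p = 0.00253) and gluconeogenesis genes 2 of 13 higher and 1 lower (8 and 2 over the list alone; 0.36, adjusted p = 0.0277), both with an adjusted p = 0.524 with an estimated correlation. The gluconeogenesis call ended without control array 1 (adjusted p = 0.0543), control array 2 (0.0883) or minor trauma array 3 (0.162), and the hypoxia call without control array 1 (0.0661), minor trauma array 3 (0.36) or shock array 2 (0.0553). Outside the called lists, 4 of 28 cytochrome P450 and conjugation genes rose (5 over the list alone; adjusted p = 0.261): Cyp2b10, Cyp3a13 (0.93 ± 0.22), the receptor gene Nr1i2 (0.86 ± 0.22) and Fmo5 (0.59 ± 0.16). Of 15 p53 targets 3 rose, Plk3, Gadd45a and Fas (4 higher and 2 lower over the list alone; adjusted p = 0.137), and 0 of 18 clock genes changed, with 2 higher and 2 lower over the list alone.

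In all, 265 genes were higher and 176 lower after minor trauma, 169 of them by at least 2-fold. This count rested on single arrays. It was 80, 73, 109, 284 and 1223 without control arrays 1 to 5 in turn, 931 and 853 without minor trauma arrays 1 and 2, and 0 by limma without minor trauma array 3 (1685 of 12771 genes at an unadjusted p under 0.05). Without the array labelled control 5 it split into 666 higher and 557 lower, with 440 genes called in the same direction with all arrays. In that fit the log2 fold change of Cyp2b10 was 6.88 (adjusted p = 1.36e-08) and that of Lcn2 5.49 (1.73e-06). Those of Mt2, Gadd45b, Cxcl1, Mt1, Nrg4 and S100a8 were 4, 3.95, 3.9, 3.54, 3.13 and 2.97 (adjusted p = 7.82e-06 to 0.000191), against 3.16, 3.23, 3.13, 2.81, 2.49 and 2.33 with all arrays. There p53 targets were also called (adjusted p = 0.0431), and with minor trauma array 3 left out as well 411 genes were higher and 385 lower. The count was 326 with the poly-A set as a block and 212 within the spiked set. Within the other set, with 1 minor trauma array assumed to vary like the other groups, limma called 0 (718 of 11990 at an unadjusted p under 0.05). Values as deposited gave 218 higher and 12 lower (94.8% higher against 60.1%), and median centring 450 and 152 (74.8%).

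Shock with severe trauma was compared with control to show the liver at the end of shock. Cxcl2, a neutrophil-attracting chemokine, rose 46.8-fold (log2 5.55 ± 0.42, adjusted p = 3.07e-08, n = 4 against 5), Gadd45b 43.9-fold, the stress transcription factor Atf3 39.5-fold (5.30 ± 0.24, adjusted p = 1.25e-11) and Jun 36.9-fold. The first 3 folds depend on the pseudocount: without one and with one of 18 the log2 change was 6.31 and 4.74 for Cxcl2, 6.73 and 4.62 for Gadd45b, and 5.78 and 4.68 for Atf3. The cytokine gene Il6 rose at least 10.4-fold (adjusted p = 5.58e-07), and Fos, Egr1, S100a8, S100a9 and the G-protein regulator Rgs16 rose 14.7-fold to 21.3-fold (adjusted p from 6.42e-10 to 0.000141). Inhbe, which encodes the liver-secreted inhibin beta E subunit, fell most, 4.79-fold (-2.26 ± 0.22, adjusted p = 6.99e-07), followed by the lipolysis inhibitor G0s2 (4-fold), the transcription factor genes Zfp503 (at least 2.12-fold) and Sox18 (3.27-fold), Tmem25 (3.16-fold) and the clock gene Per3 (2.94-fold). Zfp950 fell 2.42-fold, and Tepsin, B3galt4 and Arhgef15 at least 1.01-fold, 1.2-fold and 1.47-fold. On the shock arrays Sox18 lay above the median on 2 of 4 and Per3 on 3. For these 20 genes the shock and control arrays did not overlap, but the calls of Per3, Tepsin, B3galt4 and Arhgef15 ended when any 1 of 4, 6, 4 and 1 arrays was left out.

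Of 30 immediate early genes 22 rose and 0 fell (23 adjusted over the list alone; median 1.87, camera adjusted p = 2.27e-59). Glucocorticoid-inducible genes had 11 of 20 higher (16 over the list alone; 1.42, adjusted p = 5.15e-24), with Cdkn1a at 2.91 ± 0.49 and Mt2 at 3.05 ± 0.65. Neutrophil markers had 9 of 12 higher (10 over the list alone; 1.26, adjusted p = 3.13e-16), with Clec4e at least 2.21-fold higher. NF-kB targets moved with them, 13 of 32 higher (19 over the list alone; 0.92, adjusted p = 9.26e-24), with Ccl3 at least 4.18-fold higher and Il1b at 3.60 ± 0.38. IL-6 family signalling had 6 of 18 higher (7 over the list alone; 0.51, adjusted p = 7.84e-09), among them the feedback inhibitor Socs3 (2.58 ± 0.52), while p53 targets had 5 of 15 higher (6 higher and 2 lower over the list alone; 0.28, adjusted p = 7.93e-07), among them Btg2 (3.57 ± 0.20) and Gadd45a (3.44 ± 0.29). Hypoxia-inducible genes had 6 of 28 higher (13 over the list alone; 0.44, adjusted p = 3.09e-10, adjusted p = 0.0554 with an estimated correlation), led by the mTOR inhibitor Ddit4 (3.67 ± 0.32), Bhlhe40 (2.52 ± 0.31) and the glycolytic regulator Pfkfb3 (2.27 ± 0.46). Gluconeogenesis and cAMP-responsive genes had 3 of 13 higher (3 over the list alone; 0.11, adjusted p = 0.000336, adjusted p = 0.127 with an estimated correlation), Nr4a1, Igfbp1 and Irs2. All 3 are also members of the immediate early or the glucocorticoid-inducible list, so this is not a separate response. Stellate cell and fibroblast markers had 0 of 13 called (1 over the list alone; 0.28, adjusted p = 0.000336, adjusted p = 0.0553 with an estimated correlation). Fatty acid synthesis genes had 3 of 16 higher, Fasn (1.62 ± 0.30), Srebf1 (1.59 ± 0.27) and Thrsp (1.41 ± 0.34), and the same 3 over the list alone (0.17, adjusted p = 0.0129, adjusted p = 0.524 with an estimated correlation). The call ended without control array 4 (adjusted p = 0.354) or shock array 2 (0.0544). PPARalpha targets shifted down with 1 of 24 higher, Pdk4 (2.47 ± 0.43), and 1 lower, Ppara itself (1 and 2 over the list alone; -0.30, adjusted p = 0.0129, adjusted p = 0.709 with an estimated correlation). This call ended without control array 4 (adjusted p = 0.492), control array 5 (0.0589) and shock arrays 1 (0.0782) and 3 (0.057). It also ended under the 3 other scalings (adjusted p = 0.166 to 0.194). The call of Ppara ended when any 1 of 8 arrays was left out (adjusted p = 0.0573 to 0.113), control 5 among them, that of Thrsp for 6 arrays and that of Trib3 for 5. The endoplasmic reticulum stress list had 4 of 23 higher (5 over the list alone), Atf3, Ppp1r15a, Chac1 and Trib3, with a median of -0.04, a mean of 0.37 and a camera adjusted p = 0.048 (adjusted p = 0.552 with an estimated correlation). That call ended when any 1 of 11 arrays was left out (adjusted p = 0.0508 to 0.404). The acute phase proteins were not called (2 of 28 higher, Mt1 and Mt2, also over the list alone; adjusted p = 0.167), and without the array labelled control 5 they were (3 higher; adjusted p = 4.2e-05).

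**Figure D3:**
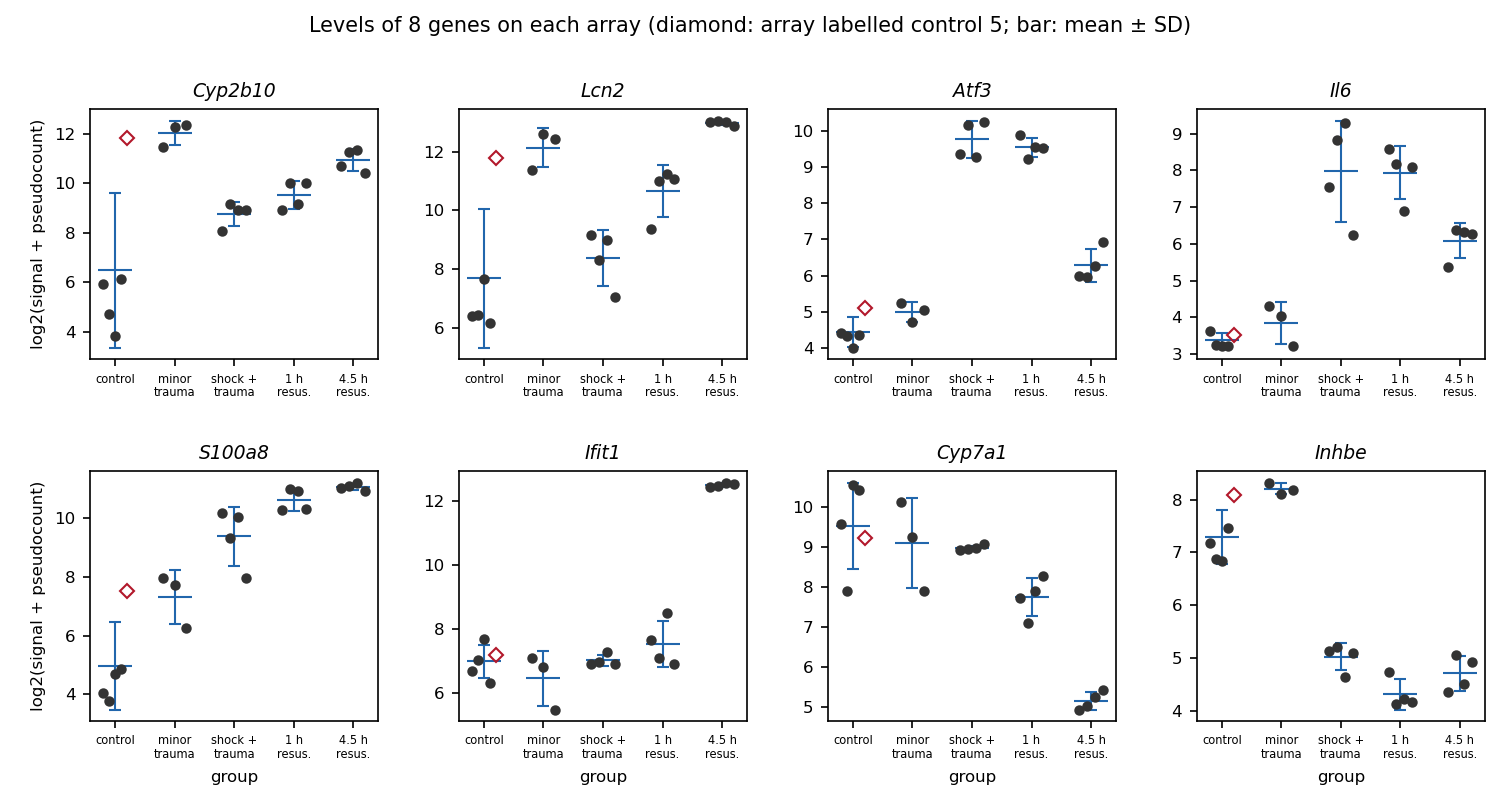
Normalized log2 level of Cyp2b10, Lcn2, Atf3, Il6, S100a8, Ifit1, Cyp7a1 and Inhbe on each of the 20 arrays (points) in the 5 groups, with group mean and SD (bars); the diamond is the array labelled control 5. Cyp2b10 averaged 12.02 in minor trauma and 8.76 in shock, and Atf3 5.01 and 9.75.

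In shock 260 genes were higher and 139 lower than in control, 208 of them by at least 2-fold. Leaving out the array labelled control 5 gave 312 and 186, with 359 genes shared, and without minor trauma array 3 as well 367 and 344. Without control 5 the log2 fold changes of Gadd45b, S100a8 and Mt2 were 6.18, 5.05 and 3.9 (adjusted p = 3.21e-08 to 4.78e-07), against 5.46, 4.41 and 3.05 with all arrays. The count fell to 251 without shock array 2 and to 248 without shock array 3. It was 376 with the poly-A set as a block, 154 within the spiked set and 53 within the other. As deposited, 171 genes were higher and 28 lower (85.9% higher against 65.2%), and trimmed mean scaling gave 55% higher.

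The group resuscitated for 1 h was compared with control to follow the response into early resuscitation. Cxcl2 rose 121-fold (6.91 ± 0.42, adjusted p = 6.99e-10, n = 4 against 5), S100a8 50.4-fold (5.66 ± 0.56, adjusted p = 3.85e-07) and S100a9 45.9-fold. Gadd45b, Atf3, the NF-kB inhibitor Tnfaip3 and Ier3 rose 30.7-fold to 34.4-fold (adjusted p from 2.81e-11 to 1.19e-05). Without a pseudocount and with one of 18 the log2 change was 7.68 and 6.08 for Cxcl2, 6.38 and 4.28 for Gadd45b, and 5.57 and 4.47 for Atf3. The chemokine gene Ccl3, the nicotinic acid receptor gene Hcar2 and Il6 rose at least 12.1-fold, 10.9-fold and 10-fold (adjusted p from 1.65e-08 to 1.7e-06). G0s2 fell most, 11.1-fold (-3.47 ± 0.30, adjusted p = 5.85e-08), Inhbe fell 7.85-fold (-2.97 ± 0.22) and the hepatic homeobox gene Hhex 6.67-fold (-2.74 ± 0.35). Tmem25, Tbx3, the clock output gene Dbp, Sox18 and the urea cycle gene Ass1 fell 3.45-fold to 3.97-fold, and Per3 and Zfp39 at least 3.14-fold and 2.1-fold. Inhbe and Sox18 lay above their array's median on 1 of 4 arrays at 1 h. Apart from Dbp and Ass1, the arrays of both groups did not overlap for these 20 genes, and Dbp was not called when any 1 of 13 arrays was left out, the array labelled control 5 among them (adjusted p = 0.0912).

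The NF-kB list rose almost as a whole, with 29 of 32 genes higher and 0 lower (30 over the list alone; median 2.17, camera adjusted p = 4.97e-53). Neutrophil markers moved with it, 10 of 12 higher (10 over the list alone; 2.25, adjusted p = 1.78e-22). Immediate early genes had 25 of 30 higher (26 higher and 1 lower over the list alone; 1.99, adjusted p = 5.75e-45), glucocorticoid-inducible genes 13 of 20 (16 over the list alone; 1.61, adjusted p = 6.87e-17), IL-6 family signalling 10 of 18 (15 over the list alone; 1.18, adjusted p = 5.7e-16) and p53 targets 7 of 15 (7 higher and 1 lower over the list alone; 0.53, adjusted p = 1.32e-07). Acute phase proteins were called here, with 9 of 28 higher (10 over the list alone; 0.26, adjusted p = 2.06e-09, adjusted p = 0.155 with an estimated correlation), including Lcn2 (2.98 ± 0.79) and the interleukin-1 receptor antagonist Il1rn (1.98 ± 0.22). Hypoxia-inducible genes had 12 of 28 higher (14 over the list alone; 0.45, adjusted p = 5.15e-10, adjusted p = 0.0692 with an estimated correlation), including the heme-degrading enzyme Hmox1 (2.43 ± 0.36) and Adm (2.31 ± 0.25). Gluconeogenesis and cAMP-responsive genes had 5 of 13 higher (6 over the list alone; 0.39, adjusted p = 4.01e-05, adjusted p = 0.0811 with an estimated correlation), and fatty acid synthesis genes 4 of 16 (4 over the list alone; 0.26, adjusted p = 0.000428, adjusted p = 0.284 with an estimated correlation). Endoplasmic reticulum stress genes had 4 of 23 higher (5 over the list alone; 0.08, adjusted p = 0.000952, adjusted p = 0.255 with an estimated correlation). Heat shock genes had 3 of 18 higher (3 higher and 1 lower over the list alone; 0.07, adjusted p = 0.0323, adjusted p = 0.305 with an estimated correlation), led by Hspa1a (3.01 ± 0.38), and this call ended without control array 1 (adjusted p = 0.123), control array 4 (0.0627) or 1 h array 3 (0.168). Interferon-induced genes had 6 of 22 higher (6 over the list alone), among them Irf1 (2.11 ± 0.17) and Mx2 (1.44 ± 0.42), with a median of -0.05, a mean of 0.28 and a camera adjusted p = 0.0323 (adjusted p = 0.524 with an estimated correlation). That call ended without control array 4 (adjusted p = 0.266) or 1 h array 3 (adjusted p = 0.264). Among cell type markers, 3 of 15 Kupffer cell and macrophage genes fell (5 over the list alone; -0.30, adjusted p = 0.0306, adjusted p = 0.454 with an estimated correlation), Slc40a1, Cd163 and Vsig4. This call ended without control array 3 (adjusted p = 0.114), control array 5 (0.0662) or 1 h array 1 (0.14), and for values as deposited (0.115). Within the spiked set its direction turned (adjusted p = 0.699). The calls of Cd163 and Vsig4 ended when any 1 of 13 and 14 arrays was left out (without control 5 Cd163 had an adjusted p = 0.105), and those of Lcn2, Mx2 and Itgb3 when any 1 of 4, 6 and 4 was. Platelet markers had 2 of 6 higher (2 over the list alone; 0.34, adjusted p = 0.0246, adjusted p = 0.11 with an estimated correlation), Itgb3 and Pf4, and lost the call without control array 4 (adjusted p = 0.0621) or 1 h array 3 (0.0802) and for values as deposited (0.0533). Bile acid genes were not called as a list (adjusted p = 0.123), but 3 of 18 fell, also over the list alone, Cyp7a1 (-1.78 ± 0.42), the rate-limiting enzyme of bile acid synthesis, and the nuclear receptor genes Nr5a2 (-0.80 ± 0.18) and Nr1h4 (-0.71 ± 0.15).

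At 1 h 591 genes were higher and 681 lower than in control, 447 of them by at least 2-fold. Omitting the array labelled control 5 gave 693 and 776, with 1158 genes shared, and without minor trauma array 3 as well 781 and 1120. The log2 fold changes of S100a8, Gadd45b and Lcn2 without control 5 were 6.29, 5.83 and 4.01 (adjusted p = 1.45e-09 to 1.97e-06), against 5.66, 5.11 and 2.98 with all arrays. The count was 1230 with the poly-A set as a block, 446 within the spiked set and 290 within the other. Of the 260 genes higher in shock 226 were also higher at 1 h, and of the 139 lower 99 were also lower. Independent lists would share 11.97 and 7.377, without allowing for the shared control arrays. As deposited, 343 genes were higher and 139 lower (71.2% higher against 46.5%).

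The 4.5 h group was compared with control to show the liver late in resuscitation. Here and at 1 h, resuscitation cannot be told apart from the shock and trauma before it or from the time since injury. Slfn4, a Schlafen family gene of myeloid cells, rose at least 52.8-fold (adjusted p = 2.46e-12, n = 4 against 5), the protease inhibitor A2m at least 41.7-fold, the interferon-inducible GTPase gene Gbp2 61-fold (5.93 ± 0.25, adjusted p = 1e-12) and Ifit1 45.7-fold (5.51 ± 0.31). S100a8 rose 68.2-fold, S100a9 55.8-fold, Cmpk2 47.5-fold, Ifit2 42.1-fold, Lcn2 39.2-fold and the itaconate-producing enzyme gene Acod1 at least 14.4-fold. Cyp7a1 fell 20.7-fold (-4.37 ± 0.42, adjusted p = 6.18e-08), and G6pc, the last enzyme of glucose release, 10.1-fold (-3.33 ± 0.31, adjusted p = 3.45e-08). Tmem25 (12.7-fold), the succinate receptor Sucnr1 (10.3-fold), G0s2 (9.5-fold), Paqr7, Ddc and Gas1 (8.23-fold to 9.22-fold), Clec2h (at least 4.92-fold) and Tmie (at least 4.25-fold) also fell. Tmem25 and Paqr7 lay above their array's median on 1 of 4 arrays at 4.5 h, Gas1 on 2, and Sucnr1 and Kdr on 3. For these 20 genes the arrays of both groups did not overlap.

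All 22 measured interferon-induced genes rose (22 over the list alone; median 3.62, camera adjusted p = 2.12e-31), and Ifit3 reached 5.16 ± 0.15. NF-kB targets had 28 of 32 higher (29 over the list alone; 2.19, adjusted p = 2.93e-18), including the interferon-dependent chemokines Cxcl10 (4.57 ± 0.37) and Cxcl9 (4.35 ± 0.26), and IL-6 family signalling 15 of 18 (15 over the list alone; 1.98, adjusted p = 6.47e-09), while Il6 itself was at least 2.8-fold higher. Acute phase proteins had 21 of 28 higher (22 over the list alone; 0.81, adjusted p = 4.11e-12, adjusted p = 0.0701 with an estimated correlation), including Saa3 (4.91 ± 0.42). Immediate early genes had 20 of 30 higher (20 over the list alone; 1.04, adjusted p = 1.45e-09) and p53 targets 10 of 15 higher and 2 lower (11 and 2 over the list alone; 0.80, adjusted p = 2e-05). Hypoxia-inducible genes had 19 of 28 higher and 1 lower (the same over the list alone; 0.97, adjusted p = 1.45e-09, adjusted p = 0.0555 with an estimated correlation). Glucocorticoid-inducible genes had 14 of 20 higher and 1 lower (15 and 1 over the list alone; 1.29, adjusted p = 8.88e-07, adjusted p = 0.144 with an estimated correlation), and endoplasmic reticulum stress genes 14 of 23 and 0 (the same over the list alone; 0.70, adjusted p = 1.39e-05, adjusted p = 0.0887 with an estimated correlation), including the chaperone gene Creld2 (2.04 ± 0.28).

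Camera called 4 lists of hepatocyte functions lower in the same livers. Bile acid synthesis and transport genes had 12 of 18 lower and 1 higher (14 and 1 over the list alone; median -0.58, adjusted p = 0.000178), including Cyp8b1 (-1.92 ± 0.18) and the bile acid receptor gene Nr1h4 (-1.57 ± 0.15). Cytochrome P450 and conjugation genes had 18 of 28 lower and 2 higher, Cyp2b10 and Ahr, a call that ended without any 1 of 3 arrays (the same over the list alone; -0.30, adjusted p = 0.00131), including the CAR gene Nr1i3 (-1.86 ± 0.28). This call ended under median centring (adjusted p = 0.168), trimmed mean scaling (0.126) and values as deposited (0.232), and within the spiked set (0.0572). Urea cycle and amino acid genes had 12 of 23 lower and 3 higher (13 and 3 over the list alone; -0.25, adjusted p = 0.0179, adjusted p = 0.394 with an estimated correlation), including Afmid (-1.44 ± 0.14) and Prodh (-1.28 ± 0.15). Mitochondrial respiratory chain genes had 7 of 20 lower (7 over the list alone; -0.18, adjusted p = 0.0406, adjusted p = 0.0741 with an estimated correlation). These last 2 calls also ended under the 3 other scalings (adjusted p = 0.2 to 0.282 and 0.34 to 0.543), and the mitochondrial call without control array 3 (0.0552) and without 4.5 h arrays 1 (0.0689), 2 (0.0695) and 4 (0.0639). Camera did not call the lists that follow. Fatty acid synthesis had 7 of 16 lower and 0 higher (adjusted p = 0.136), cholesterol synthesis 6 of 17 lower and 1 higher (adjusted p = 0.198), PPARalpha targets 7 of 24 lower and 1 higher (adjusted p = 0.43), and NRF2 targets 6 of 14 lower and 2 higher (adjusted p = 0.329). Coagulation and complement had 10 of 28 lower and 3 higher (adjusted p = 0.173). Secreted hepatocyte proteins had 4 of 21 lower (adjusted p = 0.329), led by Igfals (-1.51 ± 0.18). Heat shock genes had 7 of 18 higher and 1 lower (adjusted p = 0.0567), gluconeogenesis genes 5 of 13 higher and 3 lower (adjusted p = 0.251), cell cycle genes 1 of 17 higher and 1 lower (adjusted p = 0.43) and clock genes 3 of 18 higher and 5 lower (adjusted p = 0.73). G6pc was not among the 13 gluconeogenesis genes. Adjusted over the list alone, NRF2 targets had 7 lower, coagulation and complement 11, secreted proteins 3, and gluconeogenesis 6 and clock genes 4 higher, while the other counts of these lists stayed.

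Cell type markers moved in the same arrays. Neutrophil markers had 10 of 12 higher (10 over the list alone; median 2.68, adjusted p = 1.02e-09). Monocyte markers had 5 of 8 higher and 1 lower (the same over the list alone; 1.35, adjusted p = 0.000224), with Chil3 at least 9.14-fold higher. Kupffer cell and macrophage markers had 12 of 15 lower and 1 higher (12 and 2 over the list alone; -1.32, adjusted p = 4.39e-06, adjusted p = 0.0887 with an estimated correlation), with Slc40a1 at -2.86 ± 0.16, Cd163 at -2.64 ± 0.20 and Vsig4 at -2.34 ± 0.17. Liver endothelial markers had 12 of 17 lower and 2 higher (14 and 2 over the list alone; -1.05, adjusted p = 2.36e-05, adjusted p = 0.0887 with an estimated correlation), with Kdr at -2.41 ± 0.23 and Clec4g at -1.80 ± 0.13. Hepatocyte markers had 4 of 12 lower and 2 higher (adjusted p = 0.43) and stellate cell markers 3 of 13 lower (adjusted p = 0.26). Lymphocyte markers had 3 of 12 higher and 1 lower (adjusted p = 0.288), led by Ccl5 (4.72 ± 0.31) and Gzmb (2.62 ± 0.39), platelet markers 3 of 6 higher and 0 lower (adjusted p = 0.164), and cholangiocyte markers 2 of 5 higher and 1 lower (adjusted p = 0.564). Of the markers of pancreas, muscle and adipose tissue 1 of 6 fell (adjusted p = 0.665), and of 2 erythroid markers 0 changed (adjusted p = 0.997). Adjusted over the list alone, these counts stayed the same. Erythroid markers had 0 members called in any of the 7 comparisons.

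At 4.5 h 1937 genes were higher and 3059 lower than in control, 1604 of them by at least 2-fold. When the array labelled control 5 was left out there were 2041 and 3134, with 4782 genes shared, and without minor trauma array 3 as well 2265 and 3438. In the fit without control 5 the log2 fold changes of S100a8 and Lcn2 were 6.73 and 6.32 (adjusted p = 8.78e-11 and 8.55e-10), against 6.09 and 5.29 with all arrays. The count was 4937 with the poly-A set as a block, 2643 within the spiked set and 2844 within the other, and values as deposited gave 789 higher and 2125 lower (27.1% higher against 38.8%).

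Shock with severe trauma was compared with minor trauma, the milder injury. When the minor trauma mice were sampled was not given, so severity cannot be told apart from time since injury or time of day. Atf3 rose 26.9-fold (log2 4.75 ± 0.28, adjusted p = 1.41e-09, n = 4 against 3), Cxcl2 20.6-fold, Egr1 17.8-fold, Fos 16.4-fold (4.04 ± 0.29), the starvation-induced gene Depp1 12.8-fold and Il6 at least 10.4-fold. Lcn2 was lower in shock, 13.6-fold (-3.77 ± 0.90, adjusted p = 0.0108), as were Nrg4 (9.85-fold), Inhbe (9.04-fold, -3.18 ± 0.25, adjusted p = 1.07e-07), Gnat1 (7.95-fold), Cxcl13 (7.87-fold) and Orm2 (6.95-fold). For these 12 genes the arrays of both groups did not overlap. Gnat1 and Fgf21 lay above their array's median on 2 of 4 shock arrays. Inhbe moved in opposite directions against control, by 0.91 in minor trauma (adjusted p = 0.0418) and by -2.26 in shock.

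Immediate early genes were higher in shock for 19 of 30 and lower for 1 (20 and 1 over the list alone; median 1.48, camera adjusted p = 1.67e-23). The other 9 calls were lost with an estimated correlation. NF-kB targets had 11 of 32 higher and 2 lower (14 and 3 over the list alone; 0.51, adjusted p = 3.95e-06, adjusted p = 0.539 with an estimated correlation), and neutrophil markers 3 of 12 higher (5 over the list alone; 0.63, adjusted p = 0.00148, adjusted p = 0.539 with an estimated correlation). Acute phase proteins were lower for 11 of 28 (16 lower and 1 higher over the list alone; -0.40, adjusted p = 3.95e-06, adjusted p = 0.539 with an estimated correlation). PPARalpha targets were lower for 6 of 24 (16 lower and 1 higher over the list alone; -0.73, adjusted p = 3.95e-06, adjusted p = 0.539 with an estimated correlation), including Cpt1a, the gatekeeper of mitochondrial fatty acid oxidation (-1.04 ± 0.18), and Fgf21 (-1.40 ± 0.37). Cholesterol synthesis genes had 3 of 17 higher (8 over the list alone; 0.56, adjusted p = 0.000666, adjusted p = 0.593 with an estimated correlation), including Insig1 (1.83 ± 0.22). Stellate cell markers had 3 of 13 higher (5 over the list alone; 0.29, adjusted p = 0.00788, adjusted p = 0.407 with an estimated correlation), Lrat, Col3a1 and Acta2. Glucocorticoid-inducible genes had 4 of 20 higher and 1 lower (6 and 2 over the list alone; 0.34, adjusted p = 0.00894, adjusted p = 0.636 with an estimated correlation), p53 targets 4 of 15 and 2 (6 and 2 over the list alone; 0.22, adjusted p = 0.0191, adjusted p = 0.407 with an estimated correlation), and hypoxia-inducible genes 7 of 28 and 0 (9 and 0 over the list alone; 0.24, adjusted p = 0.0195, adjusted p = 0.636 with an estimated correlation). Without minor trauma array 1 these last 3 calls ended (adjusted p = 0.186, 0.0612 and 0.186), and that of the hypoxia-inducible genes ended without minor trauma array 2 as well (0.164). Of the clock genes, 5 of 18 were higher, with Arntl at 2.43 ± 0.56 (above the median on 1 of 3 minor trauma arrays) and Npas2 at least 1.28-fold higher, and 3 lower, with Per3 at -2.08 ± 0.41 and Per2 at -1.59 ± 0.39 (not called when 1 array was left out, adjusted p = 0.0509), while the list was not called (6 higher and 4 lower over the list alone; adjusted p = 0.392). Per3 stood at -1.36 without control 5 (adjusted p = 0.00959), where another of its probe sets had the highest mean and stood for it. The calls of Fgf21, Col3a1 and Acta2 ended when any 1 of 3, 3 and 6 arrays was left out.

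In shock 536 genes were higher and 690 lower than in minor trauma, 384 of them by at least 2-fold. With the array labelled control 5 left out there were 620 and 795, with 1225 genes shared, and without minor trauma array 3 as well 508 and 543. The count fell to 741 without minor trauma array 3 and to 710 without shock array 2. It was 1148 with the poly-A set as a block, 251 within the spiked set and 3 within the other, which held 1 minor trauma array. As deposited, 122 genes were higher and 250 lower (32.8% higher against 43.7%).

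The 1 h group was set against the shock group to follow early resuscitation. No group without resuscitation was sampled at that time, so resuscitation cannot be told apart from the added 1 h since injury. Hcar2 rose 13.9-fold (log2 3.8 ± 0.41, adjusted p = 1.57e-05, n = 4 against 4), the monocyte-attracting chemokine Ccl2 11.8-fold, Rnd1 11.3-fold, Acod1 6.73-fold, Pde4b 6.54-fold and the endothelial adhesion gene Sele at least 5.28-fold. Hcar2 lay above its array's median on 1 of 4 shock arrays, and Ccl2 and Acod1 on 3. Without a pseudocount and with one of 18 the log2 change was 4.7 and 3.1 for Hcar2 and 3.47 and 2.2 for Acod1. Ddit4 fell 6.17-fold (-2.63 ± 0.34, adjusted p = 0.000147), the lipoprotein lipase regulator Angptl8 6.05-fold, Ass1 4.85-fold, the glucose-responsive gene Txnip 4.06-fold, and the transcription factor genes Klf2 and Klf4, which respond to blood flow in endothelium, 3.76-fold and 3.28-fold. For these 12 genes the arrays of both groups did not overlap. NF-kB targets had 12 of 32 higher (23 over the list alone; median 1.22, camera adjusted p = 6.59e-38), including Icam1 (2.68 ± 0.30) and Tnfaip3 (2.66 ± 0.36). Neutrophil markers moved with them, 3 of 12 higher (7 over the list alone; 1.15, adjusted p = 2.82e-12), Clec4e, Ngp and Mmp8. The Clec4e call ended when any 1 of 3 arrays was left out. IL-6 family signalling had 2 of 18 higher (5 over the list alone; 0.52, adjusted p = 1.28e-05, adjusted p = 0.191 with an estimated correlation), and acute phase proteins 2 of 28 (5 over the list alone; 0.21, adjusted p = 1.37e-09, adjusted p = 0.272 with an estimated correlation), Il1rn and Crp. Heat shock genes had 1 of 18 higher (4 over the list alone; 0.30, adjusted p = 1.1e-05, adjusted p = 0.101 with an estimated correlation), and interferon-induced genes 1 of 22 (1 over the list alone; 0.20, adjusted p = 1.1e-05, adjusted p = 0.281 with an estimated correlation), Irf1 (2.39 ± 0.18). Kupffer cell markers had 0 of 15 called (5 lower over the list alone; -0.35, adjusted p = 0.000208, adjusted p = 0.312 with an estimated correlation) and stellate cell markers 1 of 13 lower (4 over the list alone; -0.18, adjusted p = 0.0212, adjusted p = 0.281 with an estimated correlation), Hand2. The stellate call ended without shock array 3 (adjusted p = 0.0771) or 1 h array 2 (0.122). Of the immediate early genes 4 of 30 rose and 3 fell (6 and 7 over the list alone; adjusted p = 0.257).

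From shock to 1 h 112 genes rose and 48 fell, 78 and 23 of them by at least 2-fold. Leaving out the array labelled control 5 gave 140 and 57, with 158 genes shared, and without minor trauma array 3 as well 174 and 95. The count fell to 97 and 84 without shock arrays 2 and 4, and to 84 and 82 without 1 h arrays 2 and 3. It was 151 with the poly-A set as a block, 56 within the spiked set and 1 within the other, and 76 for values as deposited.

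The 4.5 h group was set against the 1 h group to follow the later course of resuscitation. No group without resuscitation was sampled at either time, so resuscitation cannot be told apart from the added time since injury or from time of day. Cmpk2, a nucleotide kinase gene induced by interferon, rose 63.8-fold (log2 6.00 ± 0.28, adjusted p = 4.12e-12, n = 4 against 4), Ifit3 40.6-fold (5.34 ± 0.16), A2m 34.7-fold, Gbp2 33.4-fold, Ifit1 31.1-fold and the interferon feedback gene Usp18 25.6-fold. Rgs16 fell 22.1-fold (-4.47 ± 0.59, adjusted p = 6.61e-06), G6pc 15.7-fold (-3.97 ± 0.33), Ddc 11.6-fold, Tubb2a 9.94-fold, the glycogen-targeting subunit Ppp1r3g 9.92-fold and Clec2h at least 5.18-fold. Cmpk2 and A2m lay above their array's median on 3 of 4 arrays at 1 h, and Ppp1r3g on 2 of 4 at 4.5 h. For these 12 genes the arrays of both groups did not overlap. Interferon-induced genes had 21 of 22 higher and 1 lower (the same over the list alone; median 3.54, camera adjusted p = 1.55e-29). Immediate early genes had 21 of 30 lower and 2 higher (the same over the list alone; -1.02, adjusted p = 1.7e-06, adjusted p = 0.0873 with an estimated correlation), with Atf3 at -3.26 ± 0.26 and Fos at -2.33 ± 0.27. NF-kB targets had 14 of 32 lower and 4 higher (15 and 5 over the list alone; adjusted p = 0.0769), with Cxcl2 at -2.28 ± 0.45 and Cxcl9 at 3.32 ± 0.28. Acute phase proteins had 13 of 28 higher (13 over the list alone; 0.33, adjusted p = 1.96e-05, adjusted p = 0.465 with an estimated correlation) and hypoxia-inducible genes 8 of 28 (8 over the list alone; 0.29, adjusted p = 0.00745, adjusted p = 0.497 with an estimated correlation), a call at adjusted p = 0.05 without 4.5 h array 4. Fatty acid synthesis genes had 10 of 16 lower (10 over the list alone; -0.72, adjusted p = 0.000291, adjusted p = 0.433 with an estimated correlation), including Srebf1 (-2.22 ± 0.29) and Fasn (-2.11 ± 0.31). Cytochrome P450 and conjugation genes had 16 of 28 lower (16 over the list alone; -0.29, adjusted p = 0.000275), and bile acid genes 11 of 18 lower and 1 higher (13 and 2 over the list alone; -0.53, adjusted p = 0.00202, adjusted p = 0.0873 with an estimated correlation). Monocyte markers had 6 of 8 higher and 1 lower (the same over the list alone; 1.15, adjusted p = 0.00109, adjusted p = 0.0873 with an estimated correlation). Kupffer cell markers had 12 of 15 lower and 1 higher, Marco (the same over the list alone; -0.93, adjusted p = 1.37e-05, adjusted p = 0.191 with an estimated correlation), and endothelial markers 13 of 17 lower (13 over the list alone; -0.82, adjusted p = 1.37e-05, adjusted p = 0.132 with an estimated correlation). Neutrophil markers had 1 of 12 lower (0 over the list alone; adjusted p = 0.716).

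From 1 h to 4.5 h 1914 genes rose and 2337 fell, 1309 of them by at least 2-fold. Omitting the array labelled control 5 gave 1957 and 2405, with 4212 genes shared, and without minor trauma array 3 as well 2255 and 2703. The count was 4208 with the poly-A set as a block, 1446 within the spiked set and 2259 within the other, and values as deposited gave 574 higher and 1158 lower (33.1% higher against 45%). Of the 260 genes higher in shock than in control, 129 fell between 1 h and 4.5 h.

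Clock genes differed between control arrays. Dbp read 7.32 and 6.44 on control arrays 1 and 2 and 9.83 and 10.14 on arrays 3 and 4, and Ciart, a repressor of the clock, 3.21 and 3.32 against 7.39 and 7.42. Arntl, the core activator, read 7.18 and 7.46 against 5.52 and 4.07. The mean absolute difference of the 18 clock genes was 0.37 between control arrays 1 and 2, 0.43 between 3 and 4, and 1.16 to 1.62 between the pairs. In shock Arntl averaged 6.96 ± 0.30 (SD, n = 4) and in minor trauma 4.53 ± 0.64 (SD, n = 3). The means of the shock group lay within the range of control arrays 1 to 4 for 11 of the 18 clock genes, and those of the minor trauma, 1 h and 4.5 h groups for 10, 12 and 9.

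**Figure D4:**
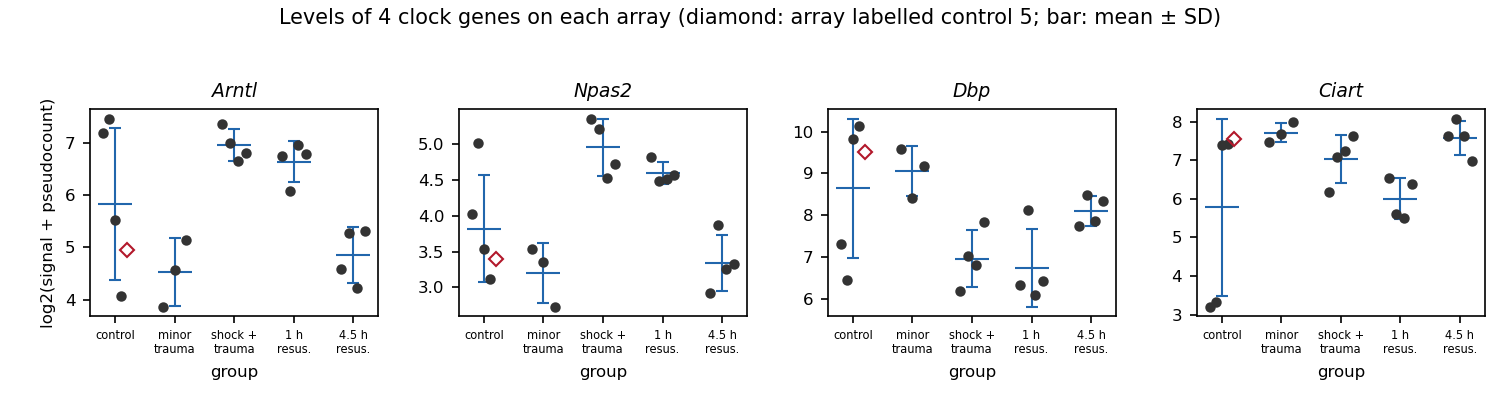
Normalized log2 level of the clock genes Arntl, Npas2, Dbp and Ciart on each of the 20 arrays (points) in the 5 groups, with group mean and SD; the diamond is the array labelled control 5. Ciart read 3.21 and 3.32 on control arrays 1 and 2 and 7.39 and 7.42 on arrays 3 and 4.

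Minor trauma and shock were also set side by side against the shared controls. Of the genes called, 45 were higher and 6 lower in both, where independent lists would share 5.37 and 1.91, and 2 were called in opposite directions. Without the array labelled control 5 these counts were 112 and 37. With control arrays 1 to 3 given to minor trauma and 4 and 5 to shock they were 34 and 2. With the reverse split limma called 0 genes for minor trauma (1239 at an unadjusted p under 0.05), so none could be shared. Across genes, which are not independent replicates, their fold changes correlated with r = 0.279, and simulated unchanged groups over the same controls gave r = 0.409. The covariance was 0.0442 against a simulated 0.025, a difference of 0.0192. In the first split r was -0.111, in the reverse split 0.162, and without control 5 0.415. Shock and the 4.5 h group shared 162 higher and 47 lower genes, where independent lists would share 39.2 and 33.1, and 44 were called in opposite directions. Simulated unchanged groups shared 0.01 in all, but had almost no calls, so that value does not measure what the shared controls add to the overlap. Their correlation across genes was 0.299, below the 0.445 of simulated unchanged groups, with a covariance of 0.0896, which was 0.0646 above the simulated one. With control arrays 1 to 3 given to shock and 4 and 5 to the 4.5 h group 159 genes were shared (r = 0.225, covariance 0.0729), and the reverse split gave 113 (r = 0.0563, covariance 0.0198). Unchanged groups simulated over the same split controls had covariances of 0.000126 and -2.12e-05.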

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

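The tests of these patterns were chosen only after the result was seen, except that of the other CAR targets. The array labelled control 5 stood at a median position of 0.83 over 304 genes chosen without it (quartiles 0.67 to 0.98), on a scale with the other controls at 0 and the minor trauma arrays at 1. Control arrays 1 to 4 stood at 0.01, -0.07, 0.21 and 0.26, and minor trauma arrays 1 to 3 at 0.66, 0.79 and 1.02. A wrong label on that array could account for the 0.83, and no table argues against it. The set without spike signal held 3 control arrays, control 5 among them, 1 minor trauma array and 2 of each other group. Counting control 5 as minor trauma would even out that set, which goes with a wrong label but does not decide it. An exchange with a minor trauma array would put such an array near the other controls. With genes chosen without control 5 the lowest stood at 0.66, which argues against an exchange. The first principal component placed the minor trauma arrays at -11.5 to -3.4 and control arrays 1 to 4 at -29.5 to -25.7. The lowest position was 0.39 with control 5 counted as a control in choosing genes, a choice that an exchange would make wrong. The poly-A set alone is argued against as the source of the 0.83. Control arrays 1 and 3, in the same set without spike signal, stood at 0.01 and 0.21. Minor trauma arrays 1 and 3 were in the other set. A smaller contribution of the set stays open.

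Clock genes differed between control arrays. Their median SD over control arrays 1 to 4 was 0.66 against 0.21 for random lists matched on expression, at percentile 100 of 10000. The poly-A set was argued against, since controls of the same set differed 1.57 times as much as those of different sets. Sampling at different times of day could account for the spread but stays open, because the percentile of 100 restates the pattern on the same arrays and the labels gave no time of day.

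Cyp2b10 and Alas1 were higher in minor trauma. If they were part of the acute phase response they should be at least as high at 4.5 h, provided that Lcn2 was higher there, but Lcn2 differed from minor trauma by 0.83 ± 0.90 (limma adjusted p = 0.528) and Saa3 by 3.94 ± 0.48 (adjusted p = 2.88e-06). The difference of Cyp2b10 was -1.1 ± 1.09 (adjusted p = 0.491) and that of Alas1 -0.65 (adjusted p = 0.438), which left this open. Activation of CAR could raise both, but 18 other CAR targets had a camera p of 0.11 in minor trauma with a median of 0.003, 1 higher and 0 lower (4 and 0 without control array 5, median -0.034), and at 4.5 h 1 higher and 13 lower. The explanations cannot be told apart with these values.

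Single arrays lay beyond the limit of Dixon's test in 14 of 148 groups of values, where chance alone gives about 1 in 20, or 7.4. On the array labelled control 5 these were the mean signals of acute phase proteins (ratio 0.741, deviation 1.22), IL-6 signalling (0.768, 0.7), p53 targets (0.753, 0.43) and neutrophil markers (0.868, 0.71). Other controls had secreted hepatocyte proteins on array 2 (0.76) and fatty acid synthesis on array 4 (0.796, deviation -0.75). In shock these were the trimmed mean signal of array 4 (0.875), secreted hepatocyte proteins on array 1 (0.839) and platelet markers on array 2 (0.855). Resuscitated arrays had acute phase proteins on 1 h array 1 (0.867, deviation -0.47) and on 4.5 h array 4 (0.908, deviation -0.23). At 4.5 h glucocorticoid-inducible genes on array 2 (0.835), cholesterol synthesis on array 3 (0.87) and interferon-induced genes on array 1 (0.837) followed.

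Some results were called in opposite directions against the same controls, and these groups were also compared directly. The results were picked for that difference, so the p values below largely restate it. PPARalpha targets were lower in shock than in minor trauma (camera p of 2.33e-07, adjusted p = 0.539 with an estimated correlation). Inhbe was lower than in minor trauma by limma in shock (-3.18, adjusted p = 1.07e-07), at 1 h (-3.89, adjusted p = 3.34e-09) and at 4.5 h (-3.49, adjusted p = 1.68e-09), with all arrays of both groups apart. Gbp6 was higher at 4.5 h than in minor trauma (5.41, adjusted p = 2.51e-10). G6pc was lower at 4.5 h than in shock (-4.85, adjusted p = 3.66e-10), and Rgs16 was lower at 4.5 h than in shock (-5.75, adjusted p = 1.81e-07) and at 1 h (-4.47, adjusted p = 6.61e-06).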

How the results depend on the processing

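Of 670 named gene results, the poly-A set as a block weakened 23, a robust fit 15, median centring 30, values as deposited 117, no trend 54, and only the arrays of the 2 groups 94. Within the spiked set 192 weakened and within the other 308. Of the 54, 57, 83, 132, 81, 35 and 115 named results called in the order of the report, 54, 13, 18, 11, 31, 10 and 17 lost the call when some single array was left out. Of 238 list results, an estimated correlation weakened 57, and fry weakened 23 and made 25 stronger. Except where construction shows it, the cause of these differences was not tested.

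Without normalization the counts were 230, 199, 482, 2914, 372, 76 and 1732 in the order of the report, and 3165 among the 5 groups. The spiked set alone gave 212, 154, 446, 2643, 251, 56 and 1446, and 2399, and the other set 0, 53, 290, 2844, 3, 1 and 2259, and 1846, with fewer arrays in each. The 0 is limma's, with 718 of 11990 genes at an unadjusted p under 0.05. Testing all probe sets, counted as probe sets, gave 702 for shock, 1958 at 1 h, 7841 at 4.5 h, 1861 for shock against minor trauma, 265 and 6460 for the steps to 1 h and 4.5 h, and 9142 among the groups. For minor trauma no filter gave 266, no trend 268, and only the arrays of the 2 groups 0 by limma (1675 of 12832 at an unadjusted p under 0.05). The last gave 280 for the step from shock to 1 h. Array weights gave 758 for shock and 412 for that step. Leaving out control array 5 with minor trauma array 3 gave 796 for minor trauma, 711 for shock and 269 for that step. Leaving out 1 array at a time gave 0 to 1223 for minor trauma, 248 to 574 for shock, 888 to 1618 at 1 h and 4467 to 5512 at 4.5 h. It gave 710 to 1612 for shock against minor trauma, 82 to 204 and 3468 to 4793 for the steps, and 5138 to 6301 among the groups.

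Replicate numbers did not pair the arrays. The 36 pairs of the same number in different groups had a median residual correlation of 0.0037 (-0.076 to 0.17) and those of other numbers -0.0036. With the replicate block the minor trauma count was 1143. Replicate 5 exists only in control, so the block removes control array 5, and no other count moved by more than 1.5 times.

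Directions turned for Rbp4 at 4.5 h under median centring (0.021), for Hspa4 in 4.5 h resuscitation versus 1 h resuscitation with the mean of its probe sets (-0.203), and for 4 lists. These were secreted hepatocyte proteins in minor trauma as deposited (adjusted p = 0.0275), Kupffer cell markers in minor trauma within the set without spike (0.0026) and at 1 h within the spiked set (0.699), and the mitochondrial chain in shock under median centring (0.0112). The correlation of minor trauma with shock over shared controls was -0.111 and 0.162 with the controls split and 0.415 without control array 5, and the overlap of shock with 4.5 h was 114 as deposited, 113 with controls 4 and 5 given to shock, and 317 without control array 5.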

Other observations

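The gene families in this part were chosen only after the result was seen, while the splits of the arrays were planned before. With other splits of the arrays, chance could not be excluded for minor trauma against control, where 4 of 56 splits gave at least its 441 genes and the highest other gave 776. That split put control array 5 with minor trauma arrays 2 and 3. No other split tried gave as many genes for shock (1 of 100 splits, 399 genes, highest other 125), 1 h (1 of 100, 1272, 1116) or 4.5 h (1 of 100, 4996, 4406). The same held for shock against minor trauma (1 of 35, 1226, 77), the steps to 1 h (1 of 35, 160, 1) and 4.5 h (1 of 35, 4251, 2) and the 5 groups (1 of 100, 5823, 1432). The 1116 and 4406 genes came from splits that set control arrays 1 to 4 against control array 5 and the resuscitated arrays. These ranks were not adjusted over the comparisons, and 1 of 35 is the lowest that 35 splits allow.

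Some gene families, which share members with the fixed lists, had several members called. Klf2, Klf4 and Klf6 are in the immediate early list, Klf9 in the glucocorticoid list, and Cyp genes in the cytochrome P450 list. The calls of these families are therefore not independent of those lists. Of 16 Klf genes 4 rose and 0 fell in shock (camera adjusted p = 2.8e-06, adjusted p = 0.00833 with an estimated correlation), but 2 rose and 1 fell at 1 h and 3 rose and 3 fell at 4.5 h (adjusted p = 0.252 and 0.946, also estimated). Of 41 Trim genes 8 fell and 0 rose at 1 h (adjusted p = 0.0238 with an estimated correlation), while 13 rose and 4 fell at 4.5 h (adjusted p = 0.0116, also estimated). Of 6 Slfn genes 5 rose and 0 fell at 4.5 h with a median of 2.34 (adjusted p = 0.00703 with an estimated correlation). Of 6 Gbp genes 5 rose and 1 fell with a median of 3.46, a call that did not hold with an estimated correlation (adjusted p = 0.0742). Of 253 Zfp genes 14 fell and 3 rose in shock with a median of -0.21 (adjusted p = 0.0447 with an estimated correlation). At 1 h 37 fell and 6 rose, and at 4.5 h 35 fell and 23 rose with a median of -0.04, without a call at an estimated correlation (adjusted p = 0.158 and 0.946). Of 16 aminoacyl-tRNA synthetase genes 9 rose and 0 fell at 4.5 h with a median of 0.40, and of 59 Cyp genes 29 fell and 2 rose. These calls did not hold with an estimated correlation (adjusted p = 0.256 and 0.0505).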
